A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

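Messenger RNA of 2 strains of the budding yeast Saccharomyces cerevisiae, X2180 and NBRC1950, was measured on 4 Affymetrix Yeast Genome 2.0 arrays, 2 for each strain. These are arrays of 1 colour on which each gene is read by a set of short probes, and the same design also carries probe sets for the fission yeast Schizosaccharomyces pombe. Per the labels' protocols, cells were grown in YPD, a rich glucose medium, RNA was extracted with hot phenol, poly(A) RNA was enriched on oligo(dT) particles, and biotin-labelled cRNA was made by the array maker's procedure. The design text says that the duplicate experiments were independent. The labels name no growth phase or cell density and no vanillin treatment, so that the strains may have been harvested in different culture states.

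The authors deposited 1 intensity value per probe set and array, on a linear scale. GCOS, the array maker's software, is the only tool that the submitters' processing notes name, and no version is given there. Whether GCOS scaled the arrays or masked probes is not given in the sources used here. The deposited intensity values had different medians and means on the 4 arrays, so no common scaling over all probe sets was visible in them. Per the design text, the authors went on in GeneSpring to divide each array by its 50th percentile and each gene by its X2180 value, and kept genes with an unadjusted p under 0.05 in a t-test. Neither division was visible in the deposited values. Detection calls were not used here.

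The array's annotation, matched to the R64 reference gene table by gene identifier, gave 1 S. cerevisiae gene for 5498 of the 10928 probe sets, several genes for 1, a gene of another species for 1746 and no gene for 3470, and 213 were control probe sets. The 5498 probe sets stood for 5449 genes. The 5217 probe sets that named no S. cerevisiae gene and were no controls served as a measure of background on each array. These counts of probe sets set what can be named, and a probe set with several genes named none.

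Deposited values were scaled per array so that the median over the S. cerevisiae probe sets was 973.6 on each, floored at a background level of 4.567, and converted to log2. The floor is the median background signal, taken over the 4 arrays. A probe set was tested when its mean over the arrays exceeded 16.35, the 90th percentile of the background probe sets, which left 5358 probe sets and 5316 genes. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets. A gene was called different at an adjusted p under 0.05. Where a gene had several probe sets, the one with the highest mean stood for it. For 9 of the 40 genes with several tested probe sets the sets differed in call, and for 0 were they called in opposite directions. Probe sets that the array maker marks as shared between similar sequences, 104 among the tested genes, cannot tell those sequences apart, and genes named from them are said to have a shared probe set.

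Positive log2 fold changes mean a higher signal in NBRC1950. Signals are means of the scaled values of 2 arrays, given with their SD. A gene whose signal was not above the 90th background percentile on either array of a strain has only a bound there. Its fold is then written as "at least N-fold": the mean log2 signal of the bright strain against, on each array of the dim strain, the higher of that percentile and the gene's own signal. The number of arrays, 2 per strain, limits the precision: the fit had 2 residual degrees of freedom per gene and borrowed 5.415 more from all genes. Same-numbered arrays of the 2 strains were not taken as pairs.

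The comparison of strains, 24 gene lists, the 16 nuclear chromosomes and the subtelomeric genes were fixed before the data were examined. Lists and chromosomes were tested with camera, a competitive test of a set against all other tested genes, with a preset correlation between genes of 0.01 and adjustment over the 24 lists or the 16 chromosomes. An estimated correlation and fry were alternatives. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of the fit, so few sets could pass. Subtelomeric genes are the 10 outermost annotated open reading frames of each chromosome arm, and were also compared with the rest by a two-sided Fisher's exact test. The R64 gene table was used for names and gene order, and no coordinates were taken from it, since the annotation of the array names no genome build. Of all the list names, 1 (AAD16) was not in that table.

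The genes named in the text follow a rule fixed with the lists: all measured members of the ergosterol list, the 10 most positive and the 10 most negative fold changes among called genes whose arrays did not overlap between strains, and up to 4 members with the smallest adjusted p in every other list. Members named beyond this rule, to spell out counts of 5 or fewer or to describe a list, were chosen after their values were seen.

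The calculation was tested on simulated data with the arrays' own means and spreads, 5352 probe sets in the fit and 200 of them changed. A far larger share was called in the data, so the rates below do not carry over to those calls. Over 20 simulations of NBRC1950 against X2180 it recovered 72.3% of the genes changed by 0.40 on the log2 scale and 96.8% of those changed by 1.00, and 7.26% of its calls were false, somewhat above the nominal 5%. Alternatives were other scalings (the median of all probe sets, none, quantile), other filters and floors, no intensity trend, the methods' t-test, a 2-fold minimum, the replicate number as a block, other set tests, the 5 or 20 outermost reading frames, and leaving out each array in turn. A count of neighbouring genes without the reading frames of Ty elements was chosen after seeing the data.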

Results

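Gene expression was compared between 2 strains of baker's yeast grown in rich medium. X2180 is a diploid laboratory strain derived from S288C, the strain of the reference genome. NBRC1950 is a strain from a Japanese culture collection. The title of the series links the ergosterol content of the cells to tolerance of vanillin, an aromatic aldehyde that arises when plant biomass is broken down and that inhibits yeast. The comparison asks which transcripts, those of ergosterol synthesis among them, differ between the strains without any treatment. Each strain was represented by 2 arrays from independent experiments. Before scaling, the median signal of the S. cerevisiae probe sets was 894 and 964 on the X2180 arrays and 983 and 1171 on the NBRC1950 arrays. Between 5259 and 5336 of 5449 genes lay above background on each array.

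The signals of a large part of the tested genes differed between the strains. Of 5316 genes tested, 2509 (47.2%) differed at an adjusted p under 0.05 in limma, 1083 higher and 1426 lower in NBRC1950. Most differences were small, with a median size of 0.48 on the log2 scale. Neither a genome of NBRC1950 nor probe sequences were used, so probes mismatched to that strain were not masked. Part of the differences may thus come from sequence and not from transcript level. In the fit, a change of at least 2-fold was seen for 140 genes that were higher and 253 that were lower. One of at least 8-fold was seen for 15 and 55 genes. These counts take fitted values also for genes below background in 1 strain, whose bounds can be smaller (FLO1, at least 6.75-fold). The arrays of one strain were close to each other: across genes, which are not independent replicates, log2 signals correlated at 0.995 for X2180 and 0.996 for NBRC1950, against 0.913 to 0.916 between strains. The SD of the log2 difference between 2 arrays was 0.20 and 0.19 within strains and 0.84 to 0.85 between them.

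How many genes counted as higher or lower depended on the scaling. With the main scaling the median gene differed by -0.05 between strains and 43.2% of the called genes were higher in NBRC1950. List and chromosome medians below are relative to that scaling. Scaled to the median of all probe sets, a median taken over the background probe sets as well, the median gene shifted to 0.50 and 3968 of 4289 called genes (92.5%) were higher. With no further scaling it shifted to 0.16 and 925 of 1308 (70.7%) were higher, and with quantile normalization 1292 of 2484 (52.0%) were. The 27 hybridization spike-in probe sets, which read added control transcripts, differed between strains by 0.07 ± 0.11 (SD over probe sets) with the main scaling. The difference was 0.62 with scaling to all probe sets and 0.28 with none. Between the 2 NBRC1950 arrays they differed by -0.207 with the main scaling and 0.0463 with none, and between the X2180 arrays by -0.0572 and 0.0522. They do not measure the amount of yeast mRNA, so they do not settle which scaling is right. Some signs of RNA composition and quality moved with the strains. All 17 probe sets for ribosomal RNA were lower in NBRC1950, by a mean of -1.10 ± 0.32 (SD over probe sets), while the X2180 arrays differed from each other by -0.39. The log2 ratio of 3' to 5' signal of SRB4 was 2.05 and 2.18 in X2180 against 2.66 and 2.83 in NBRC1950, whereas that of ACT1 was 0.20 and 0.26 against 0.33 and 0.31, that of SPT15 1.08 and 1.18 against 1.10 and 1.09, and that of WBP1 0.95 and 0.81 against 0.90 and 0.94.

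**Figure D1:**
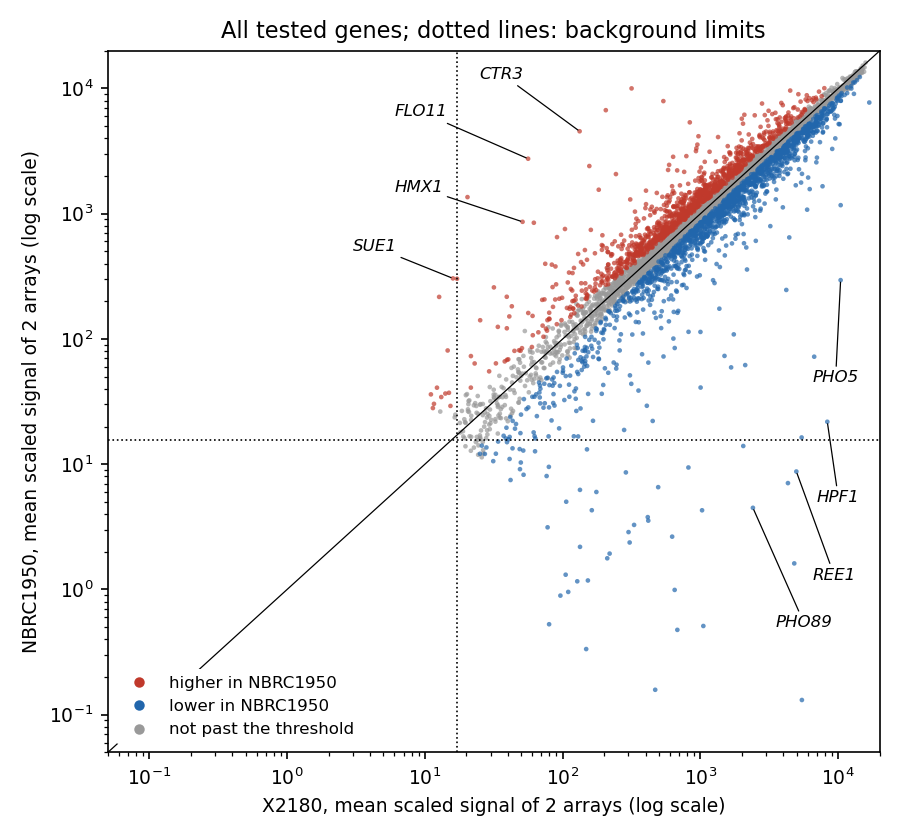
Mean scaled signal of each of 5316 tested genes in X2180 (horizontal, log scale) and NBRC1950 (vertical, log scale), 2 arrays each, before the floor used in the test, with called genes in red (1083 higher in NBRC1950) and blue (1426 lower). Dotted lines mark the background limits. The genes far below the diagonal, such as PHO89 and REE1, outnumber those far above it, such as FLO11 and CTR3. Genes outside the reference genome, that of the strain X2180 derives from, are not shown.

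The genes most strongly higher in NBRC1950 included cell surface and metal genes. The largest difference was that of YHR213W-A, an open reading frame of unknown function, at 6.06 ± 0.15 (SE; limma adjusted p = 1.69e-07), with signals of 20.4 ± 2.9 in X2180 and 1357 ± 55.5 in NBRC1950 (SD, n = 2 arrays in each strain). Its X2180 signals, 18.36 and 22.4, lay near the background limits of 18.2 and 15.92, so the size of the difference is uncertain. FLO11, a flocculin needed for adhesion and filamentous growth, rose from 56.1 ± 9.9 to 2748 ± 36.5, a difference of 5.62. CTR3, a high-affinity copper transporter, was higher by 5.11, HMX1, the heme oxygenase, by 4.07 and FRE4, a siderophore reductase, by 3.94. YER053C-A and YAR068W, both of unknown function, were higher by 5.03 and 4.98, and ECM34, above background on 1 of the 2 X2180 arrays, by 4.15. SUE1, which takes part in the degradation of unstable cytochrome c, was not above background in X2180 and at least 17.9-fold higher in NBRC1950, and YAR064W, read by a shared probe set, at least 12.7-fold higher. The adjusted p-values of these 10 genes in limma ranged from 1.25e-08 to 3.7e-05.

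The genes most strongly lower in NBRC1950 included retrotransposon reading frames and genes near chromosome ends. YDR261W-B, YAR010C, YDR316W-B and YDR261C-D, all reading frames of Ty elements with shared probe sets, were at least 339-fold, 305-fold, 274-fold and 66.4-fold lower, with no signal above background on either NBRC1950 array. REE1, which takes part in the regulation of enolase, was at least 316-fold lower and its neighbour YJL218W at least 64.9-fold lower. PHO89, a sodium-phosphate cotransporter, was at least 153-fold lower. ASP3-1, a cell wall asparaginase of a repeated locus with a shared probe set, was above background on 1 of the 2 NBRC1950 arrays and differed by -8.67, or -9.63 without NBRC1950 replicate 1 and -7.71 without NBRC1950 replicate 2. HPF1, a cell wall mannoprotein, differed by -8.58, with NBRC1950 signals of 22.46 and 21.17 near the background limits of 14.88 and 16.58. YOL159C-A was at least 43.2-fold lower. The adjusted p-values of these 10 genes in limma ranged from 6.71e-09 to 1.6e-05. The arrays cannot tell a gene that is absent or diverged in sequence from one that is not transcribed.

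Transcripts of ergosterol synthesis were higher in NBRC1950 for part of its steps. Enzymes and sterols were not measured on these arrays. Of the 27 list members, all of them measured, 13 were higher, 1 was lower and 13 did not pass the threshold, and the count was the same when adjusted over the list alone. The median difference was 0.18 and the mean 0.34, and the list stood above all other genes in camera (adjusted p = 0.000329). That call did not hold with an estimated correlation (adjusted p = 0.381 with an estimated correlation). The largest difference was that of ERG28, a scaffold of the C-4 demethylation enzymes, at 1.45 ± 0.11 (SE; limma adjusted p = 5.41e-05), with signals of 2797 ± 478 in X2180 and 7579 ± 107 in NBRC1950 (SD, n = 2 arrays in each strain). HMG1, the major HMG-CoA reductase and a control point of the pathway, was higher by 1.19 ± 0.06 (SE; limma adjusted p = 1.02e-05). MCR1 and CYB5, which pass electrons to sterol enzymes, were higher by 1.13 and 1.10. ERG5, the C-22 desaturase, was higher by 0.86, ERG29 by 0.73 and ERG7, the lanosterol synthase, by 0.65. Smaller differences were those of ERG8 (0.40), HMG2 (0.40), ERG24 (0.38), ERG12 (0.33), ERG13 (0.32) and MVD1 (0.19).

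ERG4, the reductase of the last step, was the only member lower in NBRC1950, by -0.38 ± 0.06 (SE; limma adjusted p = 0.00226), and it stood at 0.17 when scaled to all probe sets. The 13 members that did not pass were ERG1 (0.18), ERG26 (0.18), ERG20 (0.15), ERG3 (0.10), ERG25 (0.05), ERG6 (0.04), ERG9 (0.03), IDI1 (0.02), ERG11 (-0.02), ERG2 (-0.04), NCP1 (-0.06), ERG27 (-0.09) and ERG10 (-0.17). They include ERG11, the target of azole drugs, and ERG1, the squalene epoxidase. With 1 array left out, ERG1 ranged from 0.011 to 0.35 and ERG11 from -0.088 to 0.054. The differences of ERG25, IDI1, ERG2 and NCP1 also took either sign. These 13 had a median signal of 7861, against 3670 for the 13 that were higher. Of other genes at least as bright as 7861, 4.69% differed by 0.32 or more on the log2 scale, against 35.9% of those between the median gene and that level. The call of MVD1 (adjusted p = 0.0493 in limma) was lost without X2180 replicate 1 (0.0681), NBRC1950 replicate 1 (0.24) or NBRC1950 replicate 2 (0.248), and that of ERG13 without NBRC1950 replicate 1 (0.0594) or replicate 2 (0.0667). ERG1 (0.0053) and ERG26 (0.0143) passed as higher without X2180 replicate 2, ERG20 without X2180 replicate 1 (0.0399) or replicate 2 (0.0446), and ERG10 as lower without X2180 replicate 1 (0.0232).

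**Figure D2:**
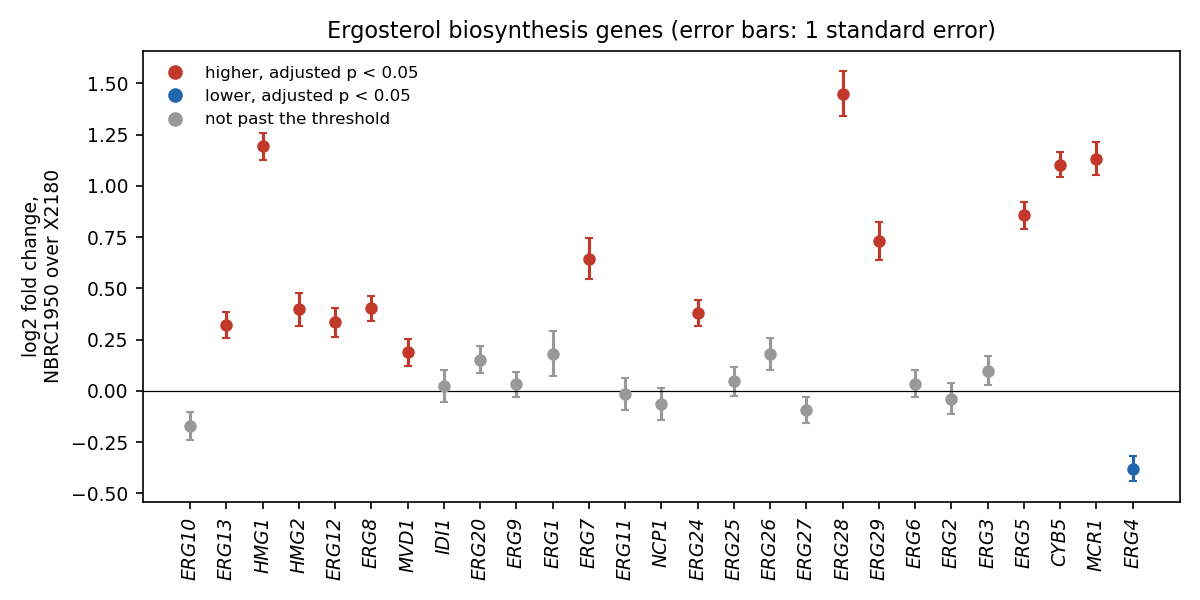
Log2 fold change, NBRC1950 over X2180, of the 27 genes of ergosterol synthesis in approximate pathway order; bars are 1 standard error from limma, n = 2 arrays per strain. Red marks the 13 genes called higher, led by ERG28 at 1.45, blue the 1 called lower (ERG4, -0.38) and grey the 13 that did not pass; scaled to all probe sets, ERG4 turned to 0.17.

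Genes of sterol regulation, uptake and storage went both ways. Of 16 measured, 6 were higher and 7 lower (6 and 7 adjusted over the list alone), with a median of 0.12 and no call in camera (adjusted p = 0.484). ARE2, the main sterol acyltransferase in aerobic cells, was higher by 1.36, SUT1, a regulator of sterol uptake, by 1.08 and NSG2, which acts on HMG-CoA reductase stability, by 0.54. AUS1, a sterol importer used without oxygen, fell by 0.98 on the log2 scale. UPC2, an activator of ergosterol genes, was at 0.22 and did not pass, nor did TGL1 (0.24) and SUT2 (0.03). The list median was -0.012 without X2180 replicate 1, 0.19 without X2180 replicate 2 and 0.070 without NBRC1950 replicate 2. Without X2180 replicate 2, TGL1 was at 0.46. Of the 7 lower members, ECM22 (limma adjusted p = 0.0188 with all arrays), NSG1 (0.0257), HES1 (0.0353) and YEH2 (0.0402) lay near the threshold. YEH2 stood at -0.16 without NBRC1950 replicate 1, against -0.24 with all arrays.

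Genes of the respiratory chain and ATP synthase, tested as 1 list, were higher in NBRC1950 as a set. Of 34 measured members, 19 were higher and 3 lower (21 and 4 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 9.24e-06; adjusted p = 0.321 with an estimated correlation). RIP1, the Rieske iron-sulfur protein of complex III, rose from 2082 ± 17.4 to 6165 ± 113 (SD, n = 2 arrays in each strain), a difference of 1.57 (limma adjusted p = 1.97e-06), and the 3 control probe sets for the same transcript differed by 1.58 to 1.81. CYC1, the main cytochrome c, was higher by 1.30 and QCR10 by 0.94. The 3 lower members were COX5B (-1.75), the form of cytochrome oxidase subunit V used at low oxygen, COX9 (-0.33) and ATP7 (-0.24). The call of COX9 was lost without NBRC1950 replicate 1 (limma adjusted p = 0.0501), and that of ATP7 without NBRC1950 replicate 1 (0.129), NBRC1950 replicate 2 (0.116) or X2180 replicate 1 (0.0886, at -0.15). The list of Hap1 and heme-responsive genes shares CYC1, CYT1, COX5A and COX5B with it and HMG1, HMG2, NCP1 and ERG11 with the ergosterol list. Of its 15 members 8 were higher and 3 lower (8 and 3 adjusted over the list alone), and it was not called (median 0.40, camera adjusted p = 0.0761). CYT1, cytochrome c1 of complex III, led the higher members at 1.92, followed by CYC1 and HMG1, and the 3 lower ones were COX5B, HAP1 (-1.06), which encodes the heme-dependent activator itself, and HEM13 (-0.83), an enzyme of heme synthesis that rises at low oxygen.

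Genes of iron uptake and of sulfate assimilation were also higher in NBRC1950. Of 22 members of the iron regulon, 16 were higher and 4 lower (17 and 4 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 2.58e-05; adjusted p = 0.29 with an estimated correlation). FRE4 and HMX1 led it, followed by SIT1, a siderophore transporter (2.17), and FET3, the multicopper oxidase of high-affinity uptake (2.05). The 4 lower members were ENB1 (-6.57), above background on 1 of the 2 NBRC1950 arrays, FIT1 (-1.88), FTH1 (-0.42) and FIT2 (-0.27). The call of FIT2 was lost without NBRC1950 replicate 1 (limma adjusted p = 0.11), NBRC1950 replicate 2 (0.165) or X2180 replicate 2 (0.157). Of 22 genes of sulfate assimilation and methionine, 15 were higher and 3 lower (16 and 3 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.00112; adjusted p = 0.29 with an estimated correlation). MET2 was higher by 1.48, MMP1, an S-methylmethionine permease, by 0.92 and MET3, the ATP sulfurylase, by 0.89. The 3 lower members were STR3 (-0.90), MET8 (-0.72) and MET17 (-0.63). Without further scaling, the call of the sulfate list was lost (adjusted p = 0.0638).

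The phosphate regulon was lower in NBRC1950 almost as a whole. Of 15 members measured, 14 were lower and 1, PHM8 (1.11), was higher (14 and 1 adjusted over the list alone), with a median of -1.46 (camera adjusted p = 4.24e-09; adjusted p = 0.29 with an estimated correlation). PHO5, the secreted acid phosphatase, fell from 10400 ± 397 to 294.9 ± 21.5 (SD, n = 2 arrays in each strain), a difference of -5.14 (limma adjusted p = 1.44e-08). SPL2, which controls low-affinity phosphate transport, differed by -6.54 and PHM6 by -5.10, next to PHO89, at least 153-fold lower. PHO84, the main high-affinity transporter, fell by 0.98. Genes of phosphate uptake, amino acid synthesis and respiration are known to change with growth phase, which the labels do not give, so strain and culture state at harvest were not separated for these lists.

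Transcripts of amino acid biosynthesis were lower in NBRC1950. Of 36 genes measured, 0 were higher and 30 lower in limma (0 and 32 adjusted over the list alone), with a median of -0.39, or 0.16 when scaled to all probe sets, where the median gene was at 0.50 (camera adjusted p = 1.51e-08; adjusted p = 0.29 with an estimated correlation). ARG1, the argininosuccinate synthetase, differed by -2.78 ± 0.10 (SE; limma adjusted p = 1.57e-06), LYS20, a homocitrate synthase, by -1.98 and LYS1, the saccharopine dehydrogenase, by -1.88. GCN4, the activator of these genes, was at -0.04 and did not pass.

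Genes of variable loci were lower in NBRC1950. Of 9 measured members of the list of copy-number-variable loci, 8 were lower, with ARR2 (-0.22) not past the threshold (0 higher and 8 lower adjusted over the list alone), at a median of -1.49 (camera adjusted p = 6.33e-05; adjusted p = 0.29 with an estimated correlation). VTH1, with a shared probe set, was at least 19.0-fold lower and AYT1, an acetyltransferase, at least 13.4-fold lower, and the sodium pump gene ENA5, also with a shared probe set, differed by -1.42. Of 10 measured genes of maltose and isomaltose use, 6 were lower and 1, the transporter MAL31 (0.81), was higher (6 and 1 adjusted over the list alone). Their median was -2.00, or -1.62 with the 5 members below background in NBRC1950 at their bounds (camera adjusted p = 0.011; adjusted p = 0.321 with an estimated correlation). MAL13 and MAL33, both activators of maltose genes, were at least 26.4-fold and 13.8-fold lower, IMA3, with a shared probe set, at least 11.1-fold lower and the transporter MAL11 at least 8.50-fold lower. The maltose call was lost without X2180 replicate 1 (adjusted p = 0.0502), without X2180 replicate 2 (0.077), where the median was -0.82, and with a filter at the 95th background percentile (0.073).

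Of 20 mating type and haploid-specific genes on the array, 16 were bright enough to be tested. Of these 16, 11 were lower in NBRC1950 and 0 higher in limma (11 and 0 adjusted over the list alone), at a median of -0.69. STE18, not tested, was above background only in NBRC1950 (signals of 30.45 and 24.6 against 10.92 and 5.931 in X2180). BAR1, a protease that degrades alpha factor, was above background on 1 of the 2 NBRC1950 arrays and differed by -1.91. RME1, a repressor of meiosis, differed by -1.87, NEJ1, a regulator of end joining, by -1.48 and STE4, the beta subunit of the pheromone G protein, by -0.72. The members that did not pass were AGA2 (-0.51), STE5 (0.21), MFA1 (0.16), SAG1 (-0.06) and MF(ALPHA)2 (0.24). Signals were dim, at 234.5 ± 17.6 for RME1 and 62.5 ± 6.8 for BAR1 in X2180 (SD, n = 2 arrays). The list was called in camera (adjusted p = 0.0273; adjusted p = 0.331 with an estimated correlation), and the call was lost without X2180 replicate 1 (0.0887), without X2180 replicate 2 (0.132), with quantile normalization (0.238) and with other filters (0.0714 and 0.073).

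The lists of aldehyde enzymes, drug transporters and oxidative stress genes were not called in camera. Of 31 aldehyde and alcohol oxidoreductases, 7 were higher and 13 lower (7 and 13 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.365). AAD3, an aryl-alcohol dehydrogenase homologue with a shared probe set, was higher by 1.63, whereas its homologue AAD6 was at least 9.56-fold lower, GRE2, a methylglyoxal reductase, fell from 1794 ± 313 to 631.6 ± 43.0 (SD, n = 2 arrays in each strain), and ALD2, an aldehyde dehydrogenase, differed by -1.02. Of 24 multidrug efflux genes, 9 were higher and 8 lower (10 and 8 adjusted over the list alone), with a median of 0.13, a mean of -0.18 and camera adjusted p = 0.567 in the direction of higher. QDR2 fell from 1669 ± 96.9 to 59.3 ± 7.8 (SD, n = 2 arrays in each strain), a difference of -4.82. RSB1 differed by -2.07 and ATR1 by -1.02, while the polyamine exporter TPO4 was higher by 1.94. Of 24 genes of oxidative stress defence, 2 (SOD2 at 0.57 and ZWF1 at 0.38) were higher and 8 lower (2 and 8 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.26). GTT1, a glutathione transferase, differed by -1.08, TRX2, a thioredoxin, by -0.95 and TRR1, its reductase, by -0.64. TRR1 was at -0.10 and not called when arrays were scaled to all probe sets. Single arrays moved the medians of these lists, that of the oxidoreductases to -0.15 without X2180 replicate 2, that of efflux genes to 0.21 without NBRC1950 replicate 1 and 0.034 without NBRC1950 replicate 2, and that of oxidative stress genes to -0.095 without NBRC1950 replicate 1.

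**Figure D3:**
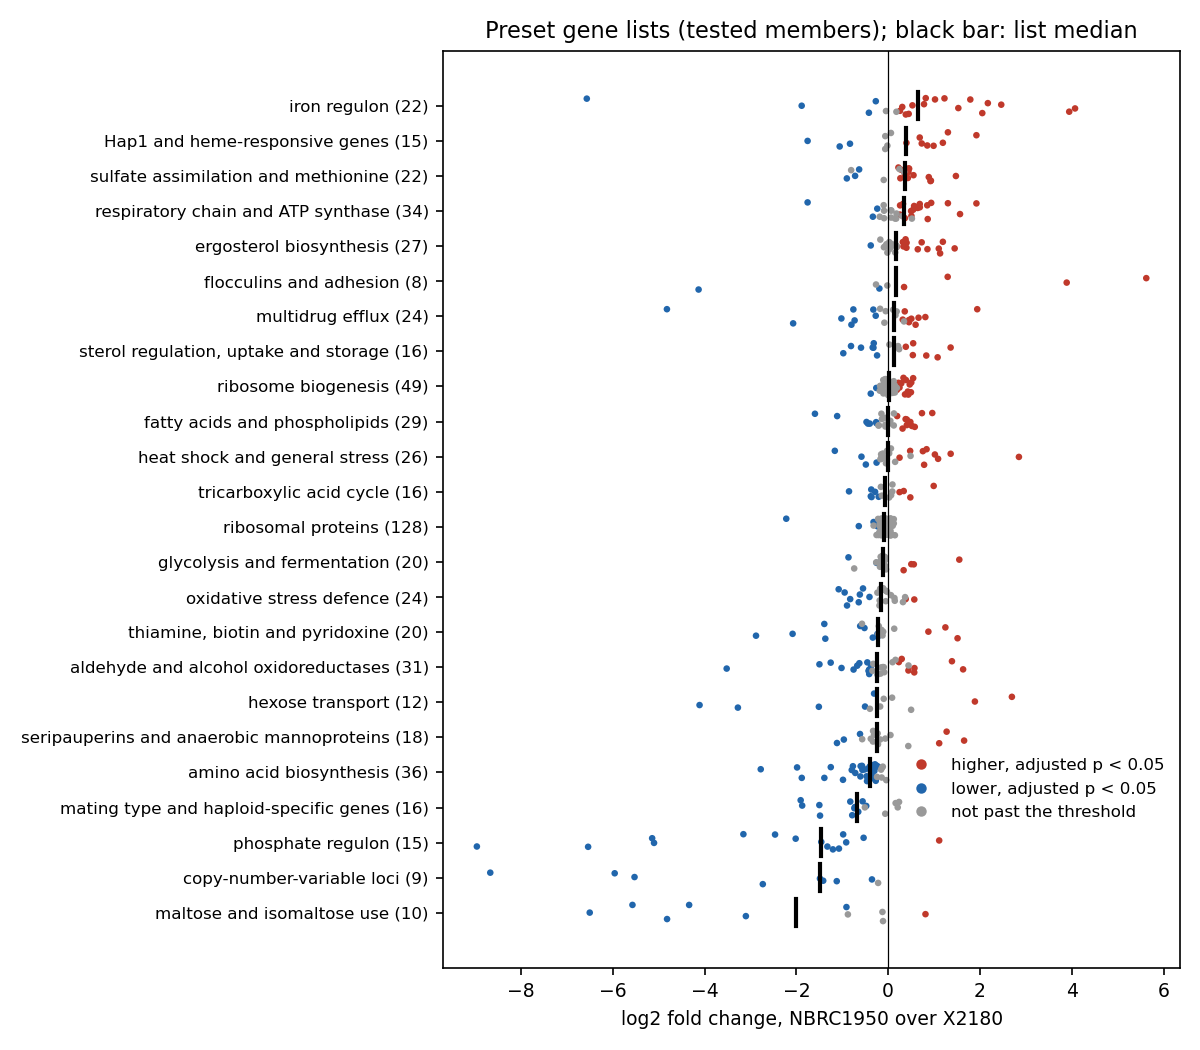
Log2 fold change, NBRC1950 over X2180 (horizontal), of each tested member of the 24 gene lists, ordered by list median (black bars), with the number of tested members in brackets and called genes in red (higher) or blue (lower). The medians run from -2.00 for maltose genes (-0.82 without X2180 replicate 2, which is closer to 0 than the medians of the phosphate and copy-number-variable lists) to 0.66 for the iron regulon; scaled to all probe sets, all move up with the median gene, that of ribosomal proteins from -0.09 to 0.46, and the medians of -0.39 and above turn positive.

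Among the 16 chromosomes, I and V stood above the rest in NBRC1950. Of 84 genes tested on chromosome I, 48 were higher and 15 lower (48 and 16 adjusted over the chromosome alone), with a median of 0.38 (camera adjusted p = 4.47e-06). Of 253 genes on chromosome V, 122 were higher and 36 lower (126 and 37 adjusted over the chromosome alone), with a median of 0.23 (camera adjusted p = 1.39e-07). With an estimated correlation neither was called (adjusted p = 0.339 for both), and without further scaling chromosome I was not (adjusted p = 0.051). The medians of the other chromosomes lay between -0.10 and -0.02, all above 0 when scaled to all probe sets, and none was called in camera (adjusted p = 0.699 to 0.983), whose direction was higher for XII, XIII, XIV and XVI. With 1 array left out, the median of VI ranged from -0.18 to -0.044 and that of XIV from -0.033 to -0.0097. Each chromosome was also divided into 4 consecutive segments with nearly equal numbers of genes. Along chromosome V, the medians of the segments were 0.24, 0.20, 0.27 and 0.23. Along chromosome I they were -0.01, 0.68, 0.49 and 0.17, against a highest segment median of 0.06 on any other chromosome. ERG28 lies on chromosome V.

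**Figure D4:**
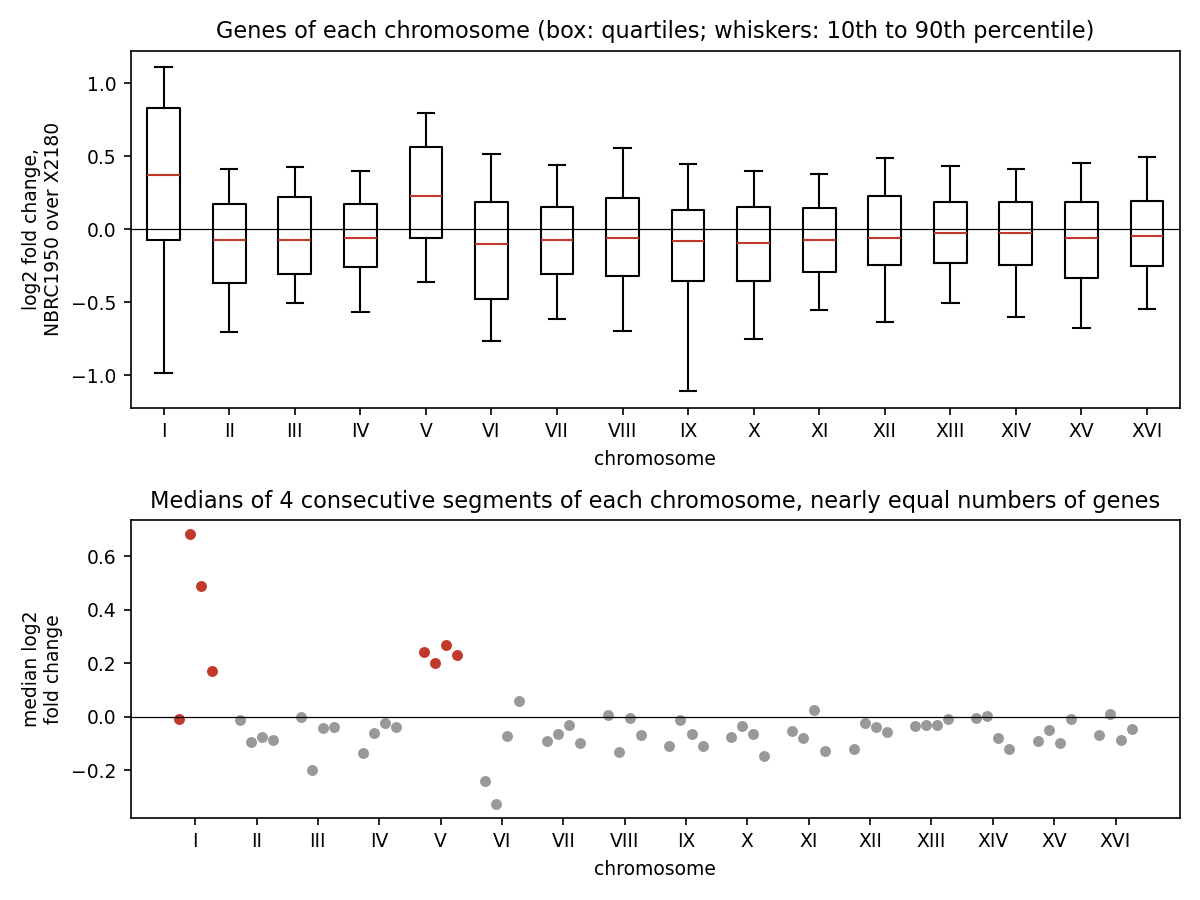
Log2 fold change, NBRC1950 over X2180, of tested genes by chromosome (top; line, median; box, quartiles; whiskers, 10th to 90th percentile) and the medians of 4 consecutive segments of each chromosome's genes in chromosome order (bottom). Chromosomes I and V (red points) have medians of 0.38 and 0.23, against -0.10 to -0.02 for the others.

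Genes near chromosome ends differed more often than others. Of 222 subtelomeric genes tested, 140 (63.1%) were called, 43 higher and 97 lower (46 and 102 adjusted over the set alone), against 46.5% of the remaining genes (odds ratio 1.96, 95% confidence interval 1.48 to 2.63, two-sided Fisher's exact p = 1.33e-06). A fitted change of at least 2-fold was seen for 18 that were higher and 56 that were lower. Their median was -0.27, or 0.27 when scaled to all probe sets, and they stood below other genes in camera (p = 0.00663; p = 0.107 with an estimated correlation; p = 0.0934 without X2180 replicate 1). The odds ratio turned to 0.68 when arrays were scaled to all probe sets, where most genes of either kind were called higher.

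Among genes of the reference table, signals above background in 1 strain only were more frequent in X2180, which derives from the reference strain. Genes outside that table that only NBRC1950 carries were out of reach, so the 2 counts below are not on equal terms. For 69 genes both X2180 arrays and neither NBRC1950 array were above background, and for 18 genes the reverse held. Of these, 50 and 11 were also called different in limma, 22 and 2 differed by at least 10-fold, and 27 and 6 were subtelomeric. The X2180 signal of 21 of the 69 was no more than 2 times the background limit, and 6 of these 21 were called. Beside the genes named above, the 69 included FLO1, HXT11, HXT9, IMA5 and STE3. FLO1, a flocculin, was at least 6.75-fold lower in NBRC1950.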

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

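All alternatives below were chosen before the data were examined. Scaled to the median of all probe sets, 4289 genes were called, 3968 higher and 321 lower, and 278 genes called under both scalings changed sign. Of the ergosterol genes 26 were then higher and 0 lower in limma (also 0 lower at an adjusted p under 0.05 with no further scaling), and the subtelomeric odds ratio was 0.68. The signs of ERG10 (0.38), ERG11 (0.53), ERG27 (0.45), ERG2 (0.51), ERG4 (0.17), NCP1 (0.48), RPS0B (0.23), RPS15 (0.31), IDH2 (0.18) and LPD1 (0.18) turned. This scaling moves all genes up by nearly the same amount by its construction, the median gene from -0.05 to 0.50. With no further scaling 1308 genes were called, 383 of them lower, and 1 chromosome (V). Unscaled medians of the S. cerevisiae probe sets differed between arrays of 1 strain (894 and 964 in X2180, 983 and 1171 in NBRC1950). That difference enters the spread within strains. How far it accounts for the lower count was not tested.

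With an estimated correlation, 0 other lists and 0 chromosomes were called in camera, 0.18 remained the ergosterol median (adjusted p = 0.381) and -0.27 the subtelomeric one (p = 0.107), since only the test changes. That alternative has 2 residual degrees of freedom, so its lost calls do not show that correlation between genes undid them. The estimate was 0.124 for the ergosterol list, above the preset 0.01. For amino acid biosynthesis it was -0.00839, below the preset, yet the unadjusted camera p rose from 1.26e-09 to 0.0195. At the preset correlation 8 other lists and 2 chromosomes were called in camera. With fry, which does not compare a set with other genes, 13 other lists and 11 chromosomes were. With the 20 outermost reading frames per arm the subtelomeric median was -0.12 and no longer past the threshold in camera. The cause was not tested. The methods' t-test gave 2071 genes at its own threshold, 885 higher and 1186 lower, and after Benjamini-Hochberg adjustment 530, 219 higher and 311 lower, a test that estimates each gene's spread from 4 arrays alone. A 2-fold minimum on the fitted values left 393 genes, 140 higher and 253 lower. Filters, floors, quantile normalization and a fit without the intensity trend gave 2260 to 2491 genes.

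Leaving out each array in turn assumes that the lone array of a strain varies like the other strain's, and gave 1835 to 2331 genes, with 0 changing sign among genes called both then and with all 4 arrays. Of the genes not called with all arrays, 10 were called higher without 1 array and lower without another, 6 of them for ribosomal proteins. The subtelomeric median then ranged from -0.32 to -0.24, and the number of lower ergosterol genes from 1 to 2, the second being ERG10 without X2180 replicate 1. With the replicate number as a block (replicate block), 2671 genes were called, against 2509. Replicate differences of the strains correlated at 0.0593 across probe sets, so the numbers were not taken as pairs. Of the calls of genes named by the fixed rule, that of MVD1 was lost under the block (limma adjusted p = 0.0507), and of the lists that of mating type and haploid-specific genes (camera adjusted p = 0.0544). Dim genes set the limit: a gene within the background range of 14.9 to 18.2 on an array has no measured level there.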

Other observations

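Of the tests below, those of dropout near background, of neighbours without Ty reading frames and of further Rox1-repressed genes were chosen only after the results were seen. Several groups of genes not yet described differed in single members, and none was called in camera. Scaled to all probe sets, where the median gene is at 0.50, the medians of all these lists were above 0. Of 128 ribosomal protein genes, 0 were higher and 5 lower in limma (0 and 2 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0761). The lower ones were RPL4B (-2.22), RPL22B (-0.64), RPS0B (-0.32), RPS15 (-0.23) and RPS6B (-0.22), the last with a shared probe set. RPL4B fell from 7687 ± 209 to 1656 ± 208 (SD, n = 2 arrays in each strain). Without X2180 replicate 1 the list median was -0.18, and without X2180 replicate 2 it was -0.0022, so single arrays decide the result of this list. The estimated correlation between these genes was 0.664, against the preset 0.01, so a small shift shared by all of them can drive its camera p. The list median of these ribosomal proteins was positive under the other scalings (0.46, 0.12 and 0.01), as were RPS0B and RPS15 scaled to all probe sets. Of 49 ribosome biogenesis genes, 13 were higher, among them UTP10 (0.55), RPA190 (0.50) and NOP16 (0.47), and 2 lower, RPA34 (-0.38) and UTP14 (-0.26), with 12 and 2 adjusted over the list alone (median 0.02, camera adjusted p = 0.161, or 0.0235 with quantile normalization). The 17 ribosomal RNA probe sets, at -1.10, went the other way, in RNA that had been enriched for poly(A). Of 26 heat shock and stress genes, 9 were higher and 4 lower (9 and 4 adjusted over the list alone; median -0.001, mean 0.26, camera direction higher, adjusted p = 0.246). HSP26 was higher by 2.85, HSP30 by 1.09 and HSP42 by 1.02, and SIS1 (-0.58), GSY2 (-1.16), STI1 (-0.49) and HSP82 (-0.25) were lower. Of these calls, those of RPS0B (limma adjusted p = 0.0713), RPS15 (0.201), RPS6B (0.271) and HSP82 (0.0906) were lost without NBRC1950 replicate 1, and those of RPS0B (0.159), RPS15 (0.332), RPS6B (0.345), HSP82 (0.0915) and UTP14 (0.0968) without NBRC1950 replicate 2. The medians near 0 turned sign without single arrays, that of ribosome biogenesis to -0.011 without X2180 replicate 2 and -0.0074 without NBRC1950 replicate 1, and that of the stress genes to 0.020, 0.065 and 0.043 without X2180 replicate 1, X2180 replicate 2 and NBRC1950 replicate 1.

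Among carbon genes, HXT4 (2.70) and HXT7 (1.89, shared probe set), hexose transporters of high affinity, were higher, and of 12 hexose transport genes 5 were lower: HXT11 (at least 5.02-fold), HXT9 (at least 4.87-fold, shared probe set), STL1, a glycerol transporter (at least 1.88-fold), RGT2, a glucose sensor (-0.50) and HXT1 (-0.31). The counts were 2 and 5 also adjusted over the list alone (median -0.24, camera adjusted p = 0.715). Of 20 glycolysis and fermentation genes, HXK1 (1.55), TDH1 (0.56), PDC5 (0.50) and GLK1 (0.34) were higher and PYK2 (-0.86) and ENO1 (-0.25) lower, which is 4 and 2, or 3 and 1 adjusted over the list alone (median -0.11, camera adjusted p = 0.687). Of 16 genes of the tricarboxylic acid cycle, SDH1 (0.99), SDH2 (0.48), KGD1 (0.34) and IDH1 (0.25) were higher and 6 lower, among them IDH2 (-0.37) and LPD1 (-0.36), with 4 and 6 also adjusted over the list alone (median -0.06, camera direction higher, adjusted p = 0.972). FLO9, a flocculin with a shared probe set, was higher by 3.89. Of 8 flocculin and adhesion genes 4 were higher (FLO11, FLO9, FLO8 at 0.35 and YHR213W, at least 1.65-fold) and 2 lower (FLO1 and SED1, at -0.19), the same adjusted over the list alone (median 0.17, camera adjusted p = 0.212, or 0.000332 with no further scaling). Of 18 seripauperin and mannoprotein genes 3 were higher (PAU2 at 1.66, shared; TIR3 at 1.27; PAU5 at 1.11) and 3 lower (PAU7 at -1.11, shared; TIR2 at -0.97; PAU17 at -0.61), the same adjusted over the list alone (median -0.24, camera adjusted p = 0.759). Of 20 thiamine, biotin and pyridoxine genes THI4 (1.51), BIO2 (0.88) and VHT1, the biotin transporter (signals of 709.6 ± 31.7 and 1684 ± 34.6), were higher and 9 lower, BIO4 (-1.39) among them, with 3 and 9 adjusted over the list alone (median -0.22, camera adjusted p = 0.224). Of 29 fatty acid and phospholipid genes 10 were higher and 7 lower (10 and 7 adjusted over the list alone; median 0.003, mean -0.004, camera direction higher, adjusted p = 0.687), with FAA1 (-1.60) and CHO2 (-1.11) lower and GPD1 (0.74) and OLE1, the fatty acid desaturase (0.58), higher. Several of these calls were lost when 1 array was left out, while the differences kept their sign. The losses listed next are only those of genes named above, and unnamed members moved too. SDH3 of the tricarboxylic acid cycle stood at -0.15 without NBRC1950 replicate 2, against -0.21 with all arrays. INO1 of the fatty acid and phospholipid list stood at 0.51 without NBRC1950 replicate 1, against 0.96. Without NBRC1950 replicate 1 the calls of ENO1 (limma adjusted p = 0.445, at -0.16), FLO8 (0.0703), HXT1 (0.0722), IDH1 (0.115), KGD1 (0.0942), RGT2 (0.0994), SED1 (0.275) and STL1 (0.0604) were lost. Without NBRC1950 replicate 2 those of ENO1 (0.082), GLK1 (0.119), IDH1 (0.0838), PDC5 (0.144) and SED1 (0.396) were. Without X2180 replicate 1 those of ENO1 (0.0544), GLK1 (0.0983), PDC5 (0.209, at 0.27) and RGT2 (0.11, at -0.33) were, and without X2180 replicate 2 those of ENO1 (0.102) and KGD1 (0.0763). List medians also turned sign, that of flocculins to -0.17 without NBRC1950 replicate 2 (0.39 and 0.31 without X2180 replicate 1 and replicate 2), that of hexose transport to 0.020 without X2180 replicate 2 (-0.15 without X2180 replicate 1 and -0.36 without NBRC1950 replicate 2), and that of fatty acids and phospholipids to -0.050, -0.00019 and -0.062 without X2180 replicate 1, X2180 replicate 2 and NBRC1950 replicate 2. The median of the seripauperin list moved to -0.10 without X2180 replicate 1, and that of the tricarboxylic acid cycle to -0.034 without X2180 replicate 2 and -0.098 without NBRC1950 replicate 2.

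The genes of chromosomes I and V lay above those of the other chromosomes in NBRC1950, and a candidate explanation is an additional copy of these chromosomes. Of the 8 segments of these chromosomes, 7 had a median above 0.06, the highest of any segment elsewhere, and the one that did not was the left end of chromosome I (-0.01). The tables argue against the signal level of the probe sets, since a median as high came up in a share of 1e-04 of 10000 random gene lists matched on signal, the smallest share they can give. Without genes changed at least 2-fold, chromosome I lay 0.36 and chromosome V 0.26 above the other 14, but a few strong genes can hardly move a median, so this decides nothing. The hypothesis was formed and tested on the same arrays and DNA content was not measured, so that copy number and a change in transcription both stay open.

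For 69 genes a signal was present in X2180 and not in NBRC1950. Chance dropout is hard to reconcile with the 48 of them over 2 times the background limit, since between the arrays of one strain 0 genes dropped from such a signal to background, but it stays open for the other 21, of which 6 were called in limma. Of the 69, 24 lay next to another of them among the genes on the array, against a median of 4 and a highest count of 16 in 10000 random draws matched on signal. Of the 24, 8 were reading frames of Ty elements, which lie in pairs, and without the 10 Ty reading frames of the set 16 of 59 lay next to another, against a median of 2 and a highest count of 13 in 10000 draws. The draws were not matched on position, and 27 of the 69 genes were subtelomeric. How much of the excess comes from crowding near chromosome ends was not tested. Examples of runs are IMA5, REE1, YJL218W and HXT9 on chromosome X, MAL11 and MAL13 on VII, and PHO89 and MAL33 on II. Such runs may be stretches of the genome that are absent from NBRC1950 or too diverged for the probes. Neighbours silenced together stay open, and the arrays cannot separate these. The run on II is short, since MAL31, next after MAL33, was higher in NBRC1950 (0.81). PHO89 also belongs to the phosphate regulon, of which 14 of 15 measured members were lower, so regulation with those genes stays open for it.

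Of the ergosterol list 13 members were higher and 13 did not pass, and cytochrome genes were higher too. Compression near the ceiling of the arrays may account for part of the split among the brighter members. Genes outside the list were compared by the share that differed by 0.32 or more on the log2 scale. In those at least as bright as 7861, the median signal of the members not called, it was 0.131 times that in genes of middle signal. A difference in ERG11 or ERG1 could thus be hidden, although highly expressed genes may also truly differ less. Members not called that were dimmer than this level, such as NCP1 (3283 in X2180, 3138 in NBRC1950) and IDI1 (5000 and 5072), are not covered. Bright members could still be called, as ERG4 was (9135 in X2180, 7025 in NBRC1950). A candidate biological explanation is lower activity of the activator Hap1 in X2180, since strains derived from S288C carry a transposon in HAP1, which predicts less Rox1 repressor and higher levels of Rox1-repressed genes there. ROX1 was higher in NBRC1950 (0.99), and AAC3 (-0.51) and ANB1 (-0.58), the genes chosen for the test, were 2 of 2 lower, as 7.20% of random pairs of tested genes would be, but of 4 other Rox1-repressed genes 2 were lower (COX5B and HEM13) and 2 higher (HMG2 at 0.40 and CYC7, which Hap1 also activates, at 0.73). The HAP1 transcript itself had the higher signal in X2180 (793.0 against 381.4, a difference of -1.06). Transcript level does not measure the activity of the protein. The Hap1 list was not called (camera adjusted p = 0.0761), and its members CTT1 (0.06) and YHB1 (-0.06) did not pass. The HAP1 sequence of either strain was not examined, so the explanation by Hap1 stays open.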
